A study of Mus musculus with 15 samples.

How the data were processed

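The libraries came from ribosomal RNA-depleted total RNA and a strand-specific library kit, per the labels' protocols, which are the same for all 15. In the Myc experiment RNAs without poly(A) tails held far smaller shares than in the Taf experiment (small non-coding RNAs 0.00662% in WT-Myc and 1.03% in WT-Taf), which goes against that label, so the protocol of those libraries is uncertain. The submitters' processing notes name Salmon 0.8.2, DESeq2 1.14.1 and the mouse build mm9, without giving each a role, and the gene annotation is not given in the sources used here. The authors deposited estimated counts per gene as whole numbers (100% of values), with 37310 genes, each with an Ensembl ID and a symbol; 3386 rows repeat a symbol. Gene symbols shared by several rows name the row with the highest mean count. The deposited normalized values, a signal on a count scale, differ from the estimated count divided by a library factor by over 1% in at least 1 library for 13386 of 27832 genes with any count, and for 10668 of 16274 genes with counts in every library. The deposited FPKM divided by the normalized value differed between libraries by over 1%, after a factor per library, in 14 of 14665 genes. The authors' TPM table was not used: 3 names in its header occur in no other table and the names of 3 samples are absent from it, so none of its 15 columns was assigned. Positions are not printed because the build of the files differs from that of the annotation at hand.

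Samples were grouped by their titles into 5 groups of 3. Counts were tested in R 4.3.3 with edgeR 4.0.16 (TMM scaling, filterByExpr, glmQLFit and glmQLFTest), with Benjamini-Hochberg adjustment and a threshold of 0.05. The 9 libraries of the Taf experiment were fitted together and the 6 of the Myc experiment together, and interactions and the comparison of wild types used all 15. The standard error of a log2 fold change is its size divided by the square root of the F statistic. The biological coefficient of variation was 4.23% in the Taf experiment and 10.2% in the Myc experiment. No pair of replicates looked like a library deposited again, since counts of every pair differed by more than sampling noise (chi-square per degree of freedom from 2.68 to 36.4 over genes with at least 20 counts summed over the pair). That does not show separate cultures. Each library was counted as 1 sample, as the labels list them.

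The design, alternatives, 32 gene lists and the rule for named genes were fixed before the data were examined. The lists hold 964 entries, of which 952 matched a gene; lists with at least 5 tested members were tested with camera in limma 3.58.1 with a correlation of 0.01, with an estimated correlation beside it. The list of 2-cell-like genes had 3 tested members and was not tested. Named genes were the targeted genes; the 6 largest rises and 6 largest falls per knockout among called genes with a mean of at least 100 counts whose 3 knockout libraries all lay on the same side of the 3 wild-type libraries, leaving out clone-like names; 7 core pluripotency and Myc family genes; up to 4 members per list by smallest p; the 4 largest differences each way in the other comparisons; and 4 genes each way called in all knockouts. Of the list members this rule names, the text gives examples, and 1 other gene it names is not reported here. Chromosomes come from GENCODE M21 (GRCm38), matched by ID for 32620 genes (87.4%).

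Alternatives were RLE scaling, library totals, no filter, DESeq2 1.42.0, a 2-fold minimum, the replicate number as a block, each library left out, all 15 libraries in a single fit, and only the groups compared. Added after seeing the data were limma-trend on log2(FPKM + 1) and log2(FPKM + 0.1), for genes with a mean FPKM of at least 0.5, limma-trend on the authors' normalized counts, and protein-coding genes only. The procedure was tested on simulated counts with 200 changed genes: for Taf5l-KO against wild type, over 15456 genes, it recovered 71.6% of 1.5-fold, 92.5% of 2-fold and 100% of 4-fold changes, and for Myc-KO, over 14401 genes, 62.7%, 85.1% and 100%. For Taf6l-KO, over 15481 genes, it recovered 83.6% of 1.5-fold, 83.6% of 2-fold and 100% of 4-fold changes. Unchanged genes made up 10 of 186 calls for Taf5l-KO, 22 of 200 for Taf6l-KO and 13 of 178 for Myc-KO, above the nominal 0.05. Figures were drawn with Python 3.11.15.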

Results

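RNA levels were measured in J1 mouse embryonic stem cells, a male line grown in serum with leukaemia inhibitory factor (LIF), in 15 libraries of 5 groups with 3 libraries each. A first experiment held Taf5l knockout, Taf6l knockout and wild-type cells (WT-Taf), and a second held Myc knockout and its own wild-type cells (WT-Myc). TAF5L and TAF6L are subunits of the SAGA coactivator complex, and MYC is a transcription factor of growth genes. Total counts per library were 17139357 to 20655500 in Taf5l-KO, 17446821 to 21767884 in Taf6l-KO, 14935631 to 20337365 in WT-Taf, 22193018 to 27650813 in Myc-KO and 17922864 to 23869375 in WT-Myc. The labels do not say whether replicates came from separate cultures or clones, so p-values measure only the spread between these libraries, which may be technical. The descriptions of the 3 Myc-KO libraries share a code whose meaning the labels do not give, and whether they come from a single clone is open.

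The targeted genes were examined first. Taf5l (ENSMUSG00000038697) was 42.5 ± 0.681 CPM (counts scaled to library size; SD, n = 3) in Taf5l-KO against 86.0 ± 1.89 in WT-Taf, a log2 fold change of -1.02 ± 0.037 (SE). Taf6l was 6.59 ± 0.556 CPM in Taf6l-KO against 26.1 ± 0.851 in WT-Taf, a log2 fold change of -1.99 ± 0.080. Myc was 29.2 ± 1.60 CPM in Myc-KO against 66.8 ± 2.08 in WT-Myc, a log2 fold change of -1.19 ± 0.060. Each targeted gene was lower in every library of its own knockout than in every matching wild-type library, and each kept a measurable level of RNA. Myc also fell in Taf5l-KO (log2 fold change -0.69) and in Taf6l-KO (-0.83), and Taf6l fell in Taf5l-KO (-0.35). Taf5l was slightly lower in Myc-KO, a call lost with library totals (-0.15, adjusted p = 0.0962) and in DESeq2 (-0.18, 0.0609). The effect nearly vanished in limma-trend on log2(FPKM + 1) (-0.040, adjusted p = 0.808) and on normalized counts (-0.041, 0.774). The call was also lost without a filter, with the replicate block and without some single libraries.

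**Figure D1:**
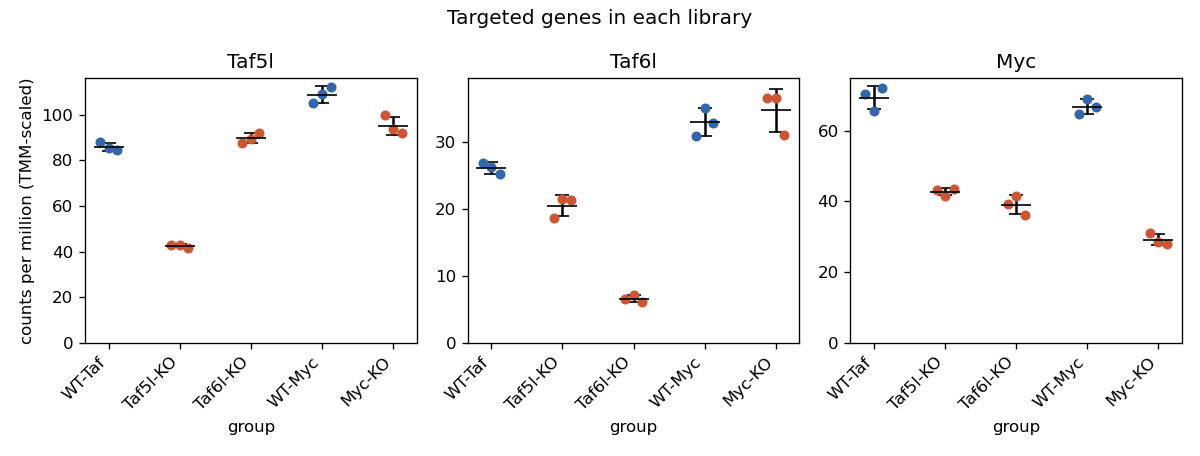
CPM of Taf5l, Taf6l and Myc (vertical axes, linear, scaled within each experiment) in the 5 groups (horizontal axis); points are libraries, and the black bars are the mean and SD of 3 libraries. Taf5l averages 42.5 in Taf5l-KO and Taf6l 6.59 in Taf6l-KO, below 86.0 and 26.1 in WT-Taf, and Myc is 29.2 in Myc-KO and 66.8 in WT-Myc.

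The Taf5l knockout was compared with wild type to ask which genes depend on TAF5L. Nrp2, a semaphorin co-receptor, rose from 4.09 ± 0.529 to 28.5 ± 0.758 CPM (SD, n = 3; log2 fold change 2.80 ± 0.083 SE). Lefty1, a secreted inhibitor of Nodal signalling, rose by 2.34 on the log2 scale, and Anxa2, a calcium-dependent membrane-binding protein, by 2.06. Grb10, an imprinted adaptor of insulin receptor signalling, fell from 172 ± 6.48 to 65.3 ± 4.51 CPM (log2 fold change -1.40), and Islr2 (-1.65), Rtn1 (-1.52), Nkx6-3 (-1.39), Cbr3 (-1.39) and Nxt2 (-1.31) fell with it. The small RNAs SNORD24 (2.60), Y_RNA (2.27) and a U3 copy (2.30) were also among the largest rises, and their values are uncertain because such RNAs have near-identical copies. Small non-coding RNAs held 1.38% ± 0.00695 of counts in Taf5l-KO against 1.03% ± 0.0854 in WT-Taf, and protein-coding genes 77.3% ± 1.39 against 79.7% ± 0.292 (SD, n = 3). Of 15743 genes tested with edgeR's quasi-likelihood test, 2735 rose and 2499 fell at a Benjamini-Hochberg adjusted p under 0.05, and 434 of these changed at least 2-fold. Rises made up 52.3% of calls, but 45.5% with library totals.

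Genes of the naive pluripotent state of mouse embryonic stem cells were lower as a group in Taf5l-KO. Of 31 tested, 17 fell and 8 rose (19 and 8 adjusted over the list alone), with camera adjusted p = 7.67e-06, and 0.0268 with an estimated correlation. Klf4 (-0.63), Jam2 (-0.69), Tdh (-0.42), Zfp42 (-0.36), Nanog (-0.27) and Esrrb (-0.27) fell, whereas Spp1 (0.43) and Sox2 (0.16) rose. Pou5f1, at -0.07 ± 0.029, did not pass the threshold (adjusted p = 0.0925). LIF-STAT3 targets fell in 7 of 13 members and rose in 1 (8 and 2 adjusted over the list alone; adjusted p = 0.000110, and adjusted p = 0.183 with an estimated correlation), including Pim1 (-0.42) and Gbx2 (-0.31). Genes of the formative and primed epiblast, the state that follows, rose in 5 of 15 members and fell in 3 (6 and 3 adjusted over the list alone; adjusted p = 0.00354, and adjusted p = 0.124 with an estimated correlation). Otx2 (1.10), Dnmt3l (0.91) and Dnmt3a (0.62) rose, and Sox3 (-1.29) fell.

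Growth-related lists were lower in Taf5l-KO by small amounts. Tested genes on the X chromosome also fell more often than they rose (177 lower and 64 higher). Members of these and the other lists, those named included, were not separated by chromosome. Falls of X-linked members may therefore be part of that wider shift. MYC targets fell in 30 of 72 members and rose in 6 (32 and 7 adjusted over the list alone; adjusted p = 0.00264, and adjusted p = 0.227 with an estimated correlation), among them the cyclin gene Ccnd2 (-1.05), Las1l (-0.42) and the replicative helicase gene Mcm5 (-0.27), while Cad rose (0.32). Ribosome biogenesis genes fell in 23 of 58 members and rose in 3 (26 and 4 adjusted over the list alone; adjusted p = 0.00354, and adjusted p = 0.290 with an estimated correlation), including Nhp2 (-0.29) and Dkc1 (-0.26). Cell cycle and DNA replication genes fell in 21 of 40 and rose in 7 (22 and 8 adjusted over the list alone; adjusted p = 0.00262, and adjusted p = 0.227 with an estimated correlation), including Mcm6 (-0.36) and Gins2 (-0.43). Nucleotide and one-carbon synthesis genes fell in 16 of 30 and rose in 3 (17 and 3 adjusted over the list alone; adjusted p = 0.00173, and adjusted p = 0.183 with an estimated correlation), including Prps2 (-0.93) and Rrm2 (-0.32). Mycn, a MYC paralog, rose in Taf5l-KO (0.37).

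Imprinted genes fell in 11 of 30 members and rose in 7 in Taf5l-KO, with the same counts adjusted over the list alone (adjusted p = 0.0182, and adjusted p = 0.15 with an estimated correlation). Mest (-0.81), Peg10 (-0.49) and H19 (-2.16) fell and Meg3 (0.63) rose. The Mest call was lost in limma-trend on log2(FPKM + 1) (adjusted p = 0.231), and H19 lies outside the rule for named genes and was named after its values were seen. H19 also did not pass the filter set for the largest falls, so its size of change is uncertain. Germline genes fell in 8 of 19 and rose in 3, with the same counts adjusted over the list alone (adjusted p = 0.0478, and adjusted p = 0.227 with an estimated correlation). Tex11 (-1.13), Sohlh2 (-0.85) and Mael (-0.71) fell and Tdrd12 (0.68) rose. The germline call was lost without Taf5l-KO replicate 1 (adjusted p = 0.0516), Taf5l-KO replicate 3 (0.0775) or WT-Taf replicate 2 (0.0670), and with protein-coding genes alone (0.0757). All 5 tested Y-linked genes rose (5 adjusted over the list alone; adjusted p = 3.29e-07, and 0.0268 with an estimated correlation), with Ddx3y at 0.84, Uty at 0.56 and Eif2s3y at 0.55. The other 21 tested lists had adjusted p from 0.0642 to 0.966. They included the markers of neuroectoderm (0.262), mesoderm (0.761), endoderm (0.533), trophectoderm (0.900) and feeder fibroblasts (0.900). The endoderm list had a positive median (0.17) and test direction but a negative mean (-0.23), the trophectoderm list a negative median (-0.079) but a positive mean (0.11) and test direction, and cytosolic ribosomal proteins a negative median and test direction but a positive mean.

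The Taf6l knockout was compared with the same wild-type libraries. Nrp2 rose from 4.09 ± 0.529 to 36.4 ± 1.68 CPM (SD, n = 3; log2 fold change 3.16 ± 0.080 SE). The Nodal inhibitors Lefty2 (2.60) and Lefty1 (2.38) rose, as did Lad1 (2.12), Anxa2 (2.06) and Calcoco2, an autophagy receptor (1.97). Grb10 fell from 172 ± 6.48 to 49.6 ± 2.98 CPM (log2 fold change -1.79), and Gpr83 (-1.60), Nkx6-3 (-1.43), Rtn1 (-1.39) and Igsf21 (-1.32) fell. Of 15743 genes tested with edgeR, 3003 rose and 2858 fell (508 and 84 of them on chromosome 11), and 497 changed at least 2-fold. With library totals in place of TMM scaling, 69.0% of calls were rises, against 51.2%.

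Naive pluripotency genes fell in 19 of 31 members and rose in 6 in Taf6l-KO (19 and 7 adjusted over the list alone; adjusted p = 7.13e-08, and 0.00948 with an estimated correlation). Nr0b1 (-0.74), Gbx2 (-0.66), Jam2 (-0.59), Klf4 (-0.58), Esrrb (-0.33), Pou5f1 (-0.22) and Zfp42 (-0.19) fell. Nanog fell by 0.11, a call lost with library totals (-0.046, adjusted p = 0.394) and without Taf6l-KO replicate 1 (-0.092, 0.0561). Sox2, at 0.08, did not pass the threshold (adjusted p = 0.0607), but did with library totals (0.14, 0.00451). LIF-STAT3 targets fell in 9 of 13 and rose in 2, with the same counts adjusted over the list alone (adjusted p = 1.09e-07, and adjusted p = 0.0783 with an estimated correlation), with Klf5 at -0.54 and Pim1 at -0.55. Targets of p53, the damage-responsive tumour suppressor, rose in 18 of 29 and fell in 3 (20 and 3 adjusted over the list alone; adjusted p = 2.50e-06, and 0.0131 with an estimated correlation), including Perp (1.07), Btg2 (0.65), Phlda3 (0.50) and Mdm2 (0.40). All 5 tested Y-linked genes rose (5 adjusted over the list alone; adjusted p = 1.03e-09, and 0.00948 with an estimated correlation), with Ddx3y at 0.89 and Eif2s3y at 0.66.

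Metabolic and growth lists were lower in Taf6l-KO, none of them past the threshold with an estimated correlation. On the X chromosome 193 tested genes were lower and 73 higher in Taf6l-KO. The members of these and the other lists, those named included, were not separated by chromosome. Falls of X-linked members in Taf6l-KO may therefore be part of the wider shift on that chromosome. ATF4 and integrated stress response genes fell in 21 of 32 and rose in 2 (23 and 2 adjusted over the list alone; adjusted p = 7.99e-07, and adjusted p = 0.105 with an estimated correlation), including Wars (-0.64) and Slc7a3 (-0.54). Cell cycle and DNA replication genes fell in 21 of 40 and rose in 6 (23 and 8 adjusted over the list alone; adjusted p = 3.97e-05, and adjusted p = 0.135 with an estimated correlation), with E2f2 at -0.79 and Mcm6 at -0.42. Nucleotide and one-carbon synthesis genes fell in 21 of 30 and rose in 4 (21 and 5 adjusted over the list alone; adjusted p = 4.67e-05, and adjusted p = 0.105 with an estimated correlation), with Prps2 at -0.65 and Shmt2 at -0.33. Oxidative phosphorylation genes fell in 16 of 38 and rose in 0, with the same counts adjusted over the list alone (adjusted p = 0.00243, and adjusted p = 0.439 with an estimated correlation), with Cox5a at -0.35. Glycolysis genes fell in 11 of 20 and rose in 4 (12 and 4 adjusted over the list alone; adjusted p = 0.00327, and adjusted p = 0.418 with an estimated correlation), with Pgk1 at -0.49. Cytosolic ribosomal protein genes fell in 34 of 74 and rose in 7 (38 and 9 adjusted over the list alone; adjusted p = 0.00327, adjusted p = 0.612 with an estimated correlation, and 0.0594 with fry), with Rps4x at -0.52.

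Another 4 lists passed in Taf6l-KO and were lost with library totals. MYC targets fell in 30 of 72 and rose in 12 (34 and 13 adjusted over the list alone; adjusted p = 0.00690, 0.15 with library totals, and adjusted p = 0.334 with an estimated correlation). Ribosome biogenesis genes fell in 24 of 58 and rose in 9 (26 and 11 adjusted over the list alone; adjusted p = 0.0431, 0.503 with library totals, and adjusted p = 0.496 with an estimated correlation). Lysosome and autophagy genes fell in 17 of 36 and rose in 6 (19 and 7 adjusted over the list alone; adjusted p = 0.0302, 0.15 with library totals, and adjusted p = 0.229 with an estimated correlation). Subunits of TFIID, the promoter-binding general transcription factor, fell in 7 of 17 and rose in 2, with the same counts adjusted over the list alone (adjusted p = 0.0297, 0.0977 with library totals, and adjusted p = 0.229 with an estimated correlation). Ccnd2 (-0.77), Dkc1 (-0.36), Ctsl (-0.43) and Taf1 (-0.45) fell among them. The ribosome biogenesis call was also lost without Taf6l-KO replicate 1 (adjusted p = 0.0799), Taf6l-KO replicate 3 (0.0546) or WT-Taf replicate 2 (0.0569), and the lysosome call without Taf6l-KO replicate 1 (0.0562). With protein-coding genes alone, ribosome biogenesis (0.0931), lysosome (0.0681) and TFIID (0.0598) were also lost. Imprinted genes fell in 9 of 30 and rose in 8, with the same counts adjusted over the list alone (adjusted p = 0.0190, and adjusted p = 0.105 with an estimated correlation). H19 rose by 4.06 on the log2 scale, opposite to its change in Taf5l-KO, while Peg10 (-0.89) and Mest (-0.71) fell. In neither Taf knockout did H19 pass the filter set for the largest rises and falls, so this contrast is uncertain.

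Replication-dependent histone genes, whose RNAs lack poly(A) tails, fell in 32 of 34 members in Taf6l-KO (33 adjusted over the list alone; median log2 fold change -0.52; adjusted p = 2.20e-16, and adjusted p = 0.319 with an estimated correlation). Hist1h3a (-0.71) and Hist1h2bb (-0.61) fell. The share of counts from these genes was 0.688% ± 0.0267 in Taf6l-KO and 0.905% ± 0.0255 in WT-Taf, and the share from small non-coding RNAs was 1.08% ± 0.167 and 1.03% ± 0.0854 (SD, n = 3). Mitochondrial ribosomal RNAs held 4.72% ± 0.256 in Taf6l-KO and 5.46% ± 0.247 in WT-Taf, lower as the histone share was. The other 15 tested lists had adjusted p from 0.106 to 0.905, among them neuroectoderm (0.524), mesoderm (0.349), endoderm (0.268), trophectoderm (0.905) and feeder fibroblasts (0.823). The endoderm list had a positive median (0.41) and test direction but a negative mean (-0.075), the neuroectoderm and germline lists a negative median and test direction but a positive mean, and immediate early genes a positive median and mean but a negative test direction.

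**Figure D2:**
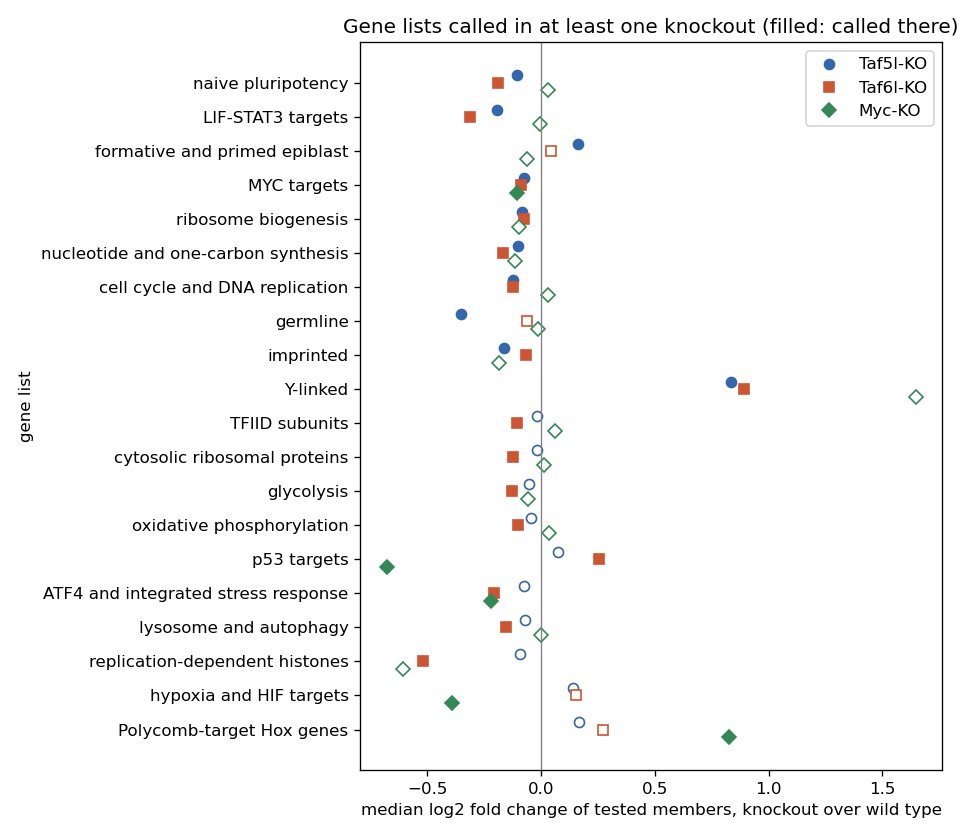
Median log2 fold change over wild type of the tested members (horizontal axis) for each gene list called in at least 1 knockout (vertical axis); circles are Taf5l-KO, squares Taf6l-KO and diamonds Myc-KO, filled where camera's adjusted p was under 0.05. The p53 targets lie at -0.68 in Myc-KO and 0.25 in Taf6l-KO, and the Y-linked list, with 4 tested members in Myc-KO, was not tested there.

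The Myc knockout was compared with its own wild-type libraries to ask which genes depend on MYC. Efhc2 rose from 1.35 ± 0.253 to 71.3 ± 17.3 CPM (SD, n = 3; log2 fold change 5.72 ± 0.233 SE). The imprinted RNA H19 (2.96), Dock10 (2.37), Clca4 (2.19), Slc11a1, a metal transporter (2.13), and D1Pas1 (2.17) rose, and D1Pas1 is uncertain because it is a near copy of the Ddx3 genes. Galnt6, which starts mucin-type glycosylation, fell from 16.4 ± 0.944 to 1.04 ± 0.286 CPM (log2 fold change -3.98), and Adamts14 (-2.50), Cyyr1 (-2.45), Sfmbt2 (-2.43), Smoc1 (-2.34) and Stc2 (-2.18) fell. Of 14563 genes tested with edgeR, 2217 rose and 2847 fell (34 and 237 of them on chromosome 14), and 885 changed at least 2-fold. Rises made up 43.8% of calls, but 52.3% with library totals and 52.0% in a fit of all 15 libraries. Myc-KO replicate 3 stood apart from its group: counts differed from replicates 1 and 2 by a chi-square per degree of freedom of 36.4 and 26.3, against 5.07 between those, and 5923 genes were called without it.

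Targets of p53 were lower as a group in Myc-KO. Of 29 tested, 26 fell and 1 rose (27 and 1 adjusted over the list alone; median log2 fold change -0.68; adjusted p = 8.10e-22, and 0.0106 with an estimated correlation). Perp (-1.68), Plk2 (-1.16) and Zmat3 (-0.83) fell. Hypoxia and HIF targets fell in 14 of 21 and rose in 1, with the same counts adjusted over the list alone (adjusted p = 1.66e-06, and adjusted p = 0.0652 with an estimated correlation), including Ddit4 (-2.04), P4ha1 (-1.21) and Vegfa, an angiogenic growth factor (-1.13). MYC targets fell in 29 of 72 and rose in 3 (30 and 4 adjusted over the list alone; adjusted p = 0.0193, and adjusted p = 0.419 with an estimated correlation), including Sord (-1.34), Ccnd2 (-1.02), Ipo4 (-0.91) and Apex1 (-0.69). Members of this and the other lists, those named included, were not separated by chromosome. Falls of members on chromosome 14 may therefore be part of its wider shift in Myc-KO (median log2 fold change -0.32). ATF4 and integrated stress response genes fell in 12 of 32 and rose in 3 (12 and 4 adjusted over the list alone; adjusted p = 0.0227, and adjusted p = 0.419 with an estimated correlation), and Asns, asparagine synthetase, was among those that rose (0.87). Polycomb-target Hox genes rose in 3 of 6, or 4 adjusted over the list alone (adjusted p = 0.0351, and adjusted p = 0.419 with an estimated correlation), with Hoxc4 at 2.31. Hoxc4 did not pass the filter of counts and separated libraries set for the largest rises, so its size of change is uncertain. Without Myc-KO replicate 3 the last 2 calls were lost, at adjusted p = 0.0773 for ATF4 genes and 0.101 for Hox genes. A fit of all 15 libraries gave 0.0764 and 0.114, and the Hox call was lost without a filter on low counts (0.0681).

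The other 25 tested lists had adjusted p from 0.0614 to 0.998 in Myc-KO. Ribosome biogenesis genes fell in 18 of 58 (19 adjusted over the list alone) without passing as a list (adjusted p = 0.0614), with Ddx21 at -1.05 and Pes1 at -0.59. The naive pluripotency list did not pass (adjusted p = 0.102). Klf4 (0.29), Zfp42 (0.31) and Spp1 (1.39) rose and Tcl1 (-0.68) fell; the Klf4 call was lost in limma-trend on log2(FPKM + 1) (adjusted p = 0.0513). Nanog was at 0.13 (adjusted p = 0.0831) and passed with RLE scaling (0.0498), library totals (0.0221), protein-coding genes alone (0.0449) and a fit of all 15 libraries (0.00318). Esrrb rose by 0.16, a call lost without Myc-KO replicate 1 (0.134) or 2 (0.136), without WT-Myc replicate 1 (0.143), 2 (0.0815) or 3 (0.0852), and on log2(FPKM + 1) (0.0740). Mycn at -0.15 (0.0533, and 0.0412 in a fit of all 15 libraries), Sox2 at 0.01 (0.907) and Pou5f1 at -0.0011 (0.992) did not pass. Imprinted Peg10 (-2.04), Sgce (-1.75) and Cdkn1c (-1.59) fell although that list did not pass (adjusted p = 0.351). Lineage marker lists did not pass (neuroectoderm 0.116, mesoderm 0.244, endoderm 0.318, trophectoderm 0.254, feeder fibroblasts 0.998), and median, mean and test differed in sign for SAGA subunits, the formative and primed epiblast, lysosome and heat shock lists. Vim (-1.52), Nodal (-1.29) and Hnf4a (-3.80) fell among the lineage markers. Hnf4a did not pass the filter of counts and separated libraries set for the largest falls, so its size of change is uncertain. The 4 tested Y-linked genes rose, with Eif2s3y at 2.09, Ddx3y at 1.69 and Uty at 1.60.

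Taf5l-KO and Taf6l-KO shared most of their calls. Of 3589 genes called in both, 1798 rose in both, 1694 fell in both and 97 went opposite ways, where independent lists would give 522 and 454. Across 15743 genes, which are not independent replicates, log2 fold changes had a Pearson correlation of 0.732. Unchanged knockouts simulated against the same wild-type libraries gave 0.512 and at most 1 shared call in 20 simulations. Few shared calls were bound to follow there, since the simulated knockouts hold no changed genes. That count therefore does not bear on the real number of shared calls. The covariance was 0.138 against a simulated 0.0197, a difference of 0.118. With 3 control libraries no split into groups of at least 2 was possible. Part of the excess of shared calls over independent lists, and of the correlation, may therefore come from the shared controls. The difference of covariances is net only of the simulated noise between libraries. A difference of the wild-type cells from both knockouts, common to the 3 control libraries, would remain in it.

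**Figure D3:**
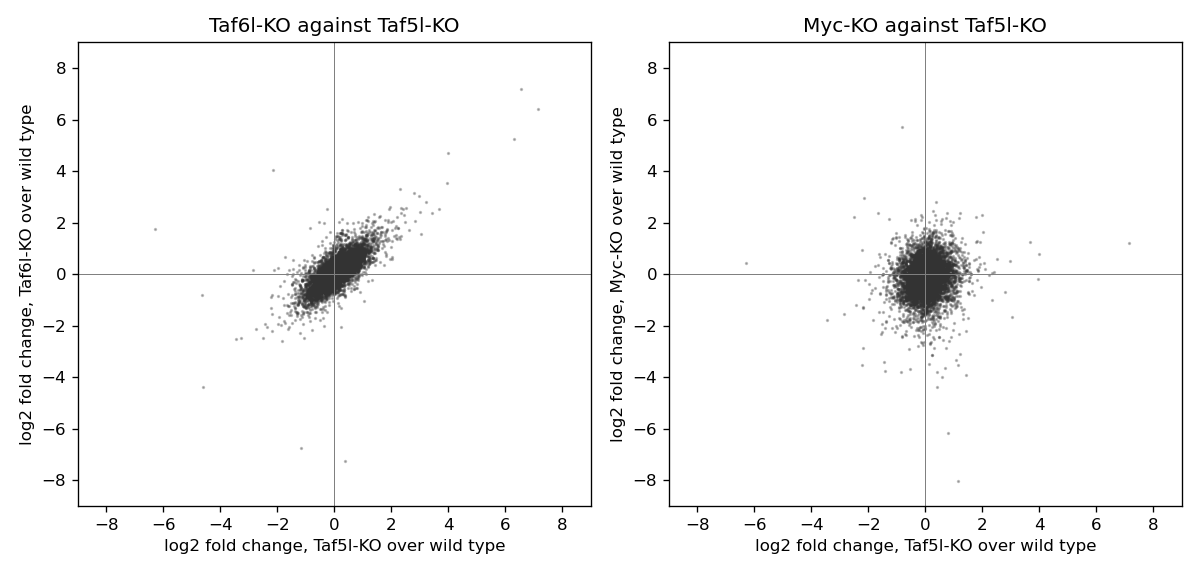
Log2 fold change over wild type of each gene tested in both comparisons (points), Taf5l-KO on the horizontal axes and Taf6l-KO (left) or Myc-KO (right) on the vertical axes. The correlation across genes is 0.732 on the left, where both share wild-type libraries, and 0.109 on the right.

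The Taf knockouts and the Myc knockout, which share no libraries, overlapped less. Of 2134 genes called in both Taf5l-KO and Myc-KO, 575 rose in both and 685 fell in both, where independent lists would give 393 and 485, and 874 went opposite ways. Of these, 557 were higher in Taf5l-KO and lower in Myc-KO, against 506 for independent lists, and 317 the reverse, against 376. Of 2338 genes called in both Taf6l-KO and Myc-KO, 547 rose and 664 fell in both, against 432 and 548, and 1127 went opposite ways. Of these, 698 were higher in Taf6l-KO and lower in Myc-KO, against 558 (Fisher's exact p = 4.08e-13 across genes, which are not independent replicates), and 429 the reverse, against 425. Fisher's exact p for genes higher in both and lower in both was 6.70e-11 and 1.27e-09 for this pair. For Taf5l-KO and Myc-KO it was 2.61e-26 and 3.91e-27. The correlations across genes were 0.109 and 0.0384. In all 3 knockouts, 374 genes rose and 479 fell. Meis2, a homeobox gene, rose by 2.01, 1.30 and 1.65 in Taf5l-KO, Taf6l-KO and Myc-KO, and Pdpn by 1.02, 1.03 and 1.39, and Myo18b and Tmem229b also rose in each. The Tmem229b calls were lost on log2(FPKM + 1) in Taf6l-KO (adjusted p = 0.0614) and Myc-KO (0.0596). The mismatch repair gene Msh6 fell in each, at -1.01, -1.04 and -1.10, and Fez2 (-1.01, -1.25 and -1.01), Naa11 (-0.91, -1.18 and -1.72) and Thumpd2 (-1.19, -0.90 and -1.17) fell with it. Of the 28 tested genes nearest Msh6 on its chromosome, 22, 22 and 23 were also called lower in these knockouts. How many of the 479 shared falls lie near Msh6 was not counted, so they may not be separate responses.

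Taf6l-KO was compared directly with Taf5l-KO. Arhgap30 (log2 fold change 1.34), Smoc1 (1.36), Mc1r, the melanocortin receptor (1.45), and Prr15 (1.27) were higher in Taf6l-KO, and the histone genes Hist1h4n (-1.04) and Hist1h2bq (-0.99) and a Y_RNA copy (-2.08) were lower. Nanog (0.15) and Zfp42 (0.17) were higher. Pou5f1 was lower (-0.15), a call lost with library totals (-0.056, adjusted p = 0.299) and in a fit of all 15 libraries (0.116). Klf4 at 0.06 did not pass (0.206), but did with library totals (0.15, 0.00903). The Mc1r call was lost on log2(FPKM + 1) (0.0640), and the Prr15 call in DESeq2 (0.0853) and on log2(FPKM + 1) (0.168). Of 15743 genes, 1346 were higher and 1592 lower in Taf6l-KO, and 117 differed at least 2-fold. With library totals 83.1% of calls were higher, against 45.8%. The p53 targets were higher in Taf6l-KO in 14 of 29 members and lower in 0 (17 and 3 adjusted over the list alone; adjusted p = 2.39e-08, and 0.0149 with an estimated correlation). Replication-dependent histone genes were lower in 31 of 34 and higher in 1 (32 and 1 adjusted over the list alone; adjusted p = 1.67e-28, and adjusted p = 0.255 with an estimated correlation), and ATF4 genes lower in 14 of 32 and higher in 0 (16 and 0 adjusted over the list alone; adjusted p = 3.84e-07, and adjusted p = 0.170 with an estimated correlation). Of 11 lists called, p53 targets alone passed with an estimated correlation.

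Differences between the Taf and Myc effects were tested as interactions in all 15 libraries, whose RNA content differed between the experiments. The p53 targets differed by a median of 0.71 on the log2 scale for Taf5l-KO minus Myc-KO, with 24 of 29 members higher (24 adjusted over the list alone; adjusted p = 9.70e-21, and 2.07e-05 with an estimated correlation). For Taf6l-KO minus Myc-KO the median was 1.00, with 25 of 29 higher (25 adjusted over the list alone; adjusted p = 5.86e-30, and 3.61e-06 with an estimated correlation). Naive pluripotency genes were lower in 15 of 31 for Taf5l-KO (15 adjusted over the list alone; median -0.14, adjusted p = 1.20e-06, and 0.0448 with an estimated correlation) and 17 of 31 for Taf6l-KO (17 adjusted over the list alone; median -0.29, adjusted p = 5.06e-07, and 0.0385 with an estimated correlation), and higher in 5 and 6 (5 and 7 adjusted over the list alone). Klf4 differed by -0.96 and -0.90. Galnt6 differed by 4.51 and 5.60, and Efhc2 by -6.58 and -6.71. In edgeR's test 5229 of 16286 genes differed for Taf5l-KO and 5665 for Taf6l-KO, of which 48.8% and 49.2% were higher in the Taf knockout. With library totals the latter share was 60.8%, and with RLE scaling the former was 52.2%.

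The wild-type groups of both experiments, from the same line, differed in 10658 of 16286 genes. The p53 targets were higher in WT-Myc than in WT-Taf in 26 of 29 members and lower in 1, with the same counts adjusted over the list alone (median log2 difference 1.23; adjusted p = 4.86e-23, and 1.34e-05 with an estimated correlation). Replication-dependent histone genes were lower in 34 of 34 (34 adjusted over the list alone; median -9.06, adjusted p = 4.73e-05 with an estimated correlation). Small non-coding RNAs held 1.03% ± 0.0854 of counts in WT-Taf and 0.00662% ± 0.000601 in WT-Myc, replication-dependent histone genes 0.905% ± 0.0255 and 0.00273% ± 5.39e-05, and mitochondrial ribosomal RNAs 5.46% ± 0.247 and 0.0537% ± 0.00842 (SD, n = 3). With library totals the median over all genes moved from -0.016 to 0.093. The labels give the same ribosomal RNA depletion for both experiments, and the low shares of RNAs without poly(A) tails in the Myc experiment go against that label. Experiment and group cannot be told apart in this comparison, and knockouts were compared only with the wild type of their own experiment.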

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

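The fits to protein-coding genes alone, to FPKM and to normalized counts and the test of the protein-coding share were chosen after the data had been seen; the other tests in this part were written down before their values were seen. The effects of the knockouts differed between the experiments by interaction tests in edgeR, which is what marks every value in the next paragraph. Library content differs between the experiments, so differences in small RNAs compare libraries as well as cells.

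For Taf5l-KO minus Myc-KO, 5229 genes differed. Among named genes the log2 differences were -0.86 for Taf5l, -0.46 for Taf6l, 0.46 for Myc, 0.47 for Mycn, 4.51 for Galnt6, -6.58 for Efhc2, -3.47 for Slc11a1, -2.23 for Stag3, -2.15 for Xaf1, -0.44 for Nanog, -0.96 for Klf4, -0.46 for Esrrb and -0.72 for Zfp42. The U4 copies differed by 8.93 and 6.86 and a U2 copy by 5.31. List medians differed by -0.19 for TFIID subunits, -0.14 for naive pluripotency, -0.18 for cell cycle and DNA replication, 0.71 for p53 targets, 0.70 for hypoxia targets and 0.46 for immediate early genes. With an estimated correlation naive pluripotency (adjusted p = 0.0448) and p53 targets (2.07e-05) passed, and TFIID (0.398), cell cycle (0.398), hypoxia (0.195) and immediate early genes (0.411) did not. For Taf6l-KO minus Myc-KO, 5665 genes differed. The log2 differences were 0.22 for Taf5l, -2.11 for Taf6l, 0.33 for Myc, 0.46 for Mycn, 5.60 for Galnt6, -6.71 for Efhc2, -3.36 for Slc11a1, -2.32 for Stag3, -0.26 for Pou5f1, -0.29 for Nanog, -0.90 for Klf4, -0.53 for Esrrb and -0.54 for Zfp42. The U4 copies differed by 9.10 and 6.61 and a U2 copy by 5.11. List medians differed by -0.22 for TFIID subunits, -0.29 for naive pluripotency, -0.21 for LIF-STAT3 targets, -0.19 for ribosomal proteins, -0.22 for oxidative phosphorylation, -0.19 for cell cycle and DNA replication, 1.00 for p53 targets and 0.59 for hypoxia targets. With an estimated correlation naive pluripotency (adjusted p = 0.0385) and p53 targets (3.61e-06) passed, and TFIID (0.260), LIF-STAT3 (0.596), ribosomal proteins (0.734), oxidative phosphorylation (0.596), cell cycle (0.185) and hypoxia targets (0.185) did not. The Taf5l call was lost without a filter (adjusted p = 0.0578), without Taf6l-KO replicate 3 (0.0505), and in limma-trend on log2(FPKM + 1) (0.174), log2(FPKM + 0.1) (0.174) and normalized counts (0.126). The Pou5f1 call was lost with library totals (0.104), without WT-Myc replicate 2 (0.0551), and on log2(FPKM + 1) (0.0538) and log2(FPKM + 0.1) (0.0555). The Myc call was lost on log2(FPKM + 1) (0.0628) and log2(FPKM + 0.1) (0.0616).

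Genes and lists were also counted in other splits of the libraries. For Taf5l-KO minus Myc-KO, 2 of 60 splits within each experiment gave as many genes as the real 5229, the real one included. The other, at 5885, was the real grouping with the Myc labels swapped, which was not drawn for Taf6l-KO. For Taf6l-KO minus Myc-KO 1 of 60 did, and the highest other gave 2732 genes. These splits relabel knockout and wild type, so they do not represent knockouts with equal effects. They therefore cannot say whether the interaction counts arise by chance. With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The real and highest other counts were 5234 and 0 genes in Taf5l-KO, 5861 and 0 in Taf6l-KO, 5064 and 0 in Myc-KO, 2938 and 1 for Taf6l-KO against Taf5l-KO, and 10658 and 1 between the wild types, with 1 of 10 splits as large in each. For lists they were 10 and 6 in Taf5l-KO and 16 and 10 in Taf6l-KO, with 1 split as large, and 5 and 7 in Myc-KO, where 3 of 10 splits called as many lists.

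The p53 targets fell in Myc-KO, with a median of -0.68, and rose in Taf6l-KO. A single library is argued against, since the median closest to 0 without a Myc-KO library was -0.65. A fit to protein-coding genes alone gave -0.66 but had little to remove. Protein-coding genes held 94.0% of counts in Myc-KO and 94.1% in WT-Myc, a log2 ratio of -0.0012 ± 0.0022 (SE). From 94.1% the share had little room to rise, so this test could not have gone with less non-polyadenylated RNA in Myc-KO. That explanation is argued against only by how little other RNA the WT-Myc libraries held. Less Trp53 transcript cannot be told apart: Trp53 was at -0.46 ± 0.0575 (SE) in Myc-KO, above the bound of -0.5 set beforehand by less than its SE. An effect of losing MYC and a difference between cell clones, with the Myc-KO libraries possibly from a single clone, both stay open and untested. The p53 targets were also higher in WT-Myc than in WT-Taf, by more than they fell in Myc-KO. The fall and the interactions both use WT-Myc as reference, and its part in them was not tested.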

How the results depend on the processing

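FPKM, normalized-count and protein-coding settings were chosen after seeing the data; the planned fits on TPM were not run, because the columns of that table were not assigned. Counts of changed genes stayed within 1.5 times under RLE scaling, library totals and no filter. The 2-fold minimum left 434, 497, 885 and 117 genes for Taf5l-KO, Taf6l-KO, Myc-KO and Taf6l-KO against Taf5l-KO, 1182 and 1364 for the interactions of Taf5l-KO and Taf6l-KO with Myc-KO, 3432 between the wild types, and 217, 40 and 36 shared calls for the pairs Taf5l and Taf6l, Taf5l and Myc, and Taf6l and Myc. limma-trend on log2(FPKM + 1) gave 2633, 3118, 3164 and 926 genes in the first 4 comparisons, and with a pseudocount of 0.1 it gave 2663, 3124, 3173 and 923, and 3457 for the Taf5l-KO interaction. Normalized counts gave 3483 for Taf5l-KO and 1406 for Taf6l-KO against Taf5l-KO, which DESeq2 put at 1942 and a fit of all 15 libraries at 1647. The cause was not tested for these. With an estimated correlation 2, 3 and 1 lists were called in Taf5l-KO, Taf6l-KO and Myc-KO, fry, which does not compare a list with other genes, called 19 in Taf5l-KO and 19 in Myc-KO, and without a filter 9 were called in Myc-KO.

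Leaving out each library in turn gave 4243 to 4751 genes for Taf5l-KO, 4933 to 5136 for Taf6l-KO, 3402 to 5923 for Myc-KO, 2022 to 2634 for Taf6l-KO against Taf5l-KO, 4478 to 5766 and 4950 to 6348 for the interactions, 9915 to 10321 between wild types, and 2800 to 3244, 916 to 1453 and 875 to 1372 shared calls. Lists numbered 9 to 12, 14 to 16 and 5 to 6. Among named genes, Apaf1 in Taf5l-KO turned to -0.02 in all limma fits (-0.0231 and -0.0235 on FPKM, -0.0235 on normalized counts) and Ep400 in Myc-KO to 0.01 (0.0101 and 0.0102 on FPKM, 0.0102 on normalized counts), none past the threshold; no other named gene changed direction under any setting in which either value was called. Apart from these changes of direction, named genes lost their calls in 1 case with RLE scaling, 11 with library totals and 7 without a filter. Losses numbered 12 with DESeq2, 6 with all 15 libraries, 2 with protein-coding genes alone, 28 on normalized counts and 62 in each FPKM fit. They numbered 20 with the replicate block, Ep400 in Myc-KO included, and 78 over all fits without 1 library. Effects under 1.5-fold and genes with few counts are limited by depth and by 3 libraries per group.

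Replicate numbers did not pair the samples throughout: correlations of same-numbered deviations were 0.0393, -0.155 and -0.120 between Taf5l-KO and WT-Taf, 0.0298, -0.150 and 0.130 between Taf6l-KO and WT-Taf, and -0.416, -0.150 and -0.607 between Myc-KO and WT-Myc. Between Taf5l-KO and Taf6l-KO they were 0.0547, 0.176 and -0.0503. There, Taf5l-KO replicates 1 and 2 correlated best with the Taf6l-KO library of their own number. Not every library correlated best with its own number. With the replicate number as a block, 5186, 5757, 3139 and 2852 genes were called for Taf5l-KO, Taf6l-KO, Myc-KO and Taf6l-KO against Taf5l-KO, 4381 and 4851 for the interactions, 8205 between wild types, 3437, 836 and 794 shared calls, and 10, 16 and 6 lists. Among the calls lost with the block were Taf5l (adjusted p = 0.0629) and Pou5f1 (0.0603) in the interaction of Taf6l-KO with Myc-KO.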

Other observations

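The look at chromosomes, the Y-linked test for a loss of the Y chromosome with its minimum of 100 counts and its repeat without each gene, and the final window of the Msh6 test were chosen after values had been seen. Chromosomes, taken from the GRCm38 annotation, did not move alike. On the X chromosome 177 of 564 tested genes were lower and 64 higher in Taf5l-KO, with a median log2 fold change of -0.13, and 193 lower and 73 higher in Taf6l-KO, with a median of -0.097, against a median of 0.019 in Myc-KO. In Taf6l-KO, 508 of 1300 tested genes on chromosome 11 were higher and 84 lower, with a median log2 fold change of 0.16, against 154 higher and 273 lower in Taf5l-KO. In Myc-KO, 237 of 483 genes on chromosome 14 were lower and 34 higher, with a median of -0.32, against 0.02 in Taf5l-KO and 0.01 in Taf6l-KO. The list tests did not separate genes by chromosome. How far these shifts enter the counts of changed genes and the list results was not tested, nor was their cause.

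Msh6 fell by about the same amount in all 3 knockouts. Scaling is argued against, since library totals alone left Msh6 at -0.97 or lower. The 28 nearest tested genes on its chromosome were 20 on one side and the 8 that remain before the chromosome ends on the other. Their medians were -0.59 ± 0.089 (SE over genes) in Taf5l-KO, -0.65 ± 0.082 in Taf6l-KO and -0.81 ± 0.092 in Myc-KO. This SE takes the 28 genes as independent, which genes of a shared segment may not be, and does not measure spread between libraries. Of these genes 22, 22 and 23 were called lower and 0 called higher. The bound set beforehand was -0.5 in each. A first version of the window, limited to better expressed genes and running on into the next chromosome, gave -0.43, -0.46 and -0.59 and did not reach that bound in the Taf knockouts. Fewer copies of this segment in the knockout lines, or more in wild type, is a candidate explanation, and an effect of the knockouts on the segment stays open.

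Y-linked genes were higher in every knockout. Scaling is argued against, as the lowest median with library totals alone was 0.81. Wild-type cultures in which some cells lack the Y chromosome would raise all expressed Y-linked genes alike; among the 4 with a mean of at least 100 counts, the smallest log2 change was 0.605, 0.411 and 0.325 of the largest in Taf5l-KO, Taf6l-KO and Myc-KO, below the bound of 0.5 in 2 comparisons. Both rest on Ube1y1: without it the ratios were 0.655, 0.659 and 0.769, while with Zfy1, at 6.07 counts on average, the lowest was 0.178, so partial loss of the Y chromosome in wild type stays open. An effect of the knockouts, shared reads with X-linked copies and clone differences stay open too, untested.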
